A study of Cryptomeria japonica with 78 samples.

How the data were processed

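The study followed gene expression through a year in Japanese cedar, *Cryptomeria japonica*, a conifer planted across Japan. Cuttings planted in the year before sampling began, in 3 regions (Yamagata, Ibaraki and Kumamoto), were sampled in each of 13 months, from February 2014 to February 2015. Each region and month had 2 samples, the tips of side branches of different cuttings, which made 39 groups and 78 samples. Total RNA was labelled with Cy3 and each sample was hybridised to its own Agilent array. The labels state neither the time of day of sampling nor the tree or clone behind each sample.

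The deposited scanner output gave, per the file headers, an intensity for each spot as extracted with Agilent Feature Extraction 11.5.1.1, after subtraction of local background and a spatial correction within the array. The array held 19304 probes, of which 15559 were printed on 3 spots and 3745 on 4 spots, and a further 1319 control spots. The deposited series table held log2 values that had been scaled to the 75th percentile of each array and centred on the median of each probe over the 78 arrays; the column medians ran from -0.239 to 0.245. Of its 78 columns, 76 matched the scanner output of the same sample, and the columns of the 2 Ibaraki samples of May 2014 matched each other's scanner output (correlation with their own 0.553). The scanner output was used, and an exchange within a group leaves the group means as they are.

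Spots that the scanner software had marked as outliers were dropped and the remaining spots of a probe were averaged. Values were taken as log2 of the processed signal minus the 75th percentile of the array. A probe counted as well above background on an array when the scanner software said so of more than a share of 0.5 of its spots. A probe was tested when this held on both arrays of at least 1 group, as for 16128 probes. The 75th percentile of the arrays ran from 207 to 1296 intensity units with a median of 674. Between 63.2% and 83.8% of the probes on an array lay well above background, and 0 spots were saturated. The number of arrays, 2 per group, limits the precision of each monthly value.

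The arrays came from 12 slides read in 7 scan runs, and 2 slides held 1 array of the series. The samples of a group were on different slides, and slides held several groups. Replicate numbers did not pair samples across groups: over the 741 pairs of groups, the correlation of the deviations of equally numbered samples had a median of -0.00229, and 36 of 78 arrays correlated better with samples of their own number. A replicate block was nevertheless tried, and it gave 6917 probes for the summer against winter contrast of the 3 regions, as without it. A code at the end of the sample titles recurs within a region in different months, and its meaning is not stated. The codes G03 and G05 occur in both Ibaraki and Kumamoto, while Yamagata shares none with them. If the code marks a tree or clone, the regions also differ in it. It was tried within regions as a random block, with an estimated correlation of 0.0593 between arrays of the same code.

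One linear model with a mean for each of the 39 groups was fitted to all 78 arrays with limma 3.58.1 in R 4.3.3, with moderated statistics from its empirical Bayes step and Benjamini-Hochberg adjustment over the probes. A probe was called when its adjusted p was under 0.05 and its log2 difference was at least 1. For the F tests of seasonality, the highest and the lowest monthly mean had to differ by at least 1. For the test of region by month, with 24 contrasts, the largest region difference had to reach 1 after its mean over the months was taken out. Summer was June, July and August 2014, and winter was February 2014, December 2014, January 2015 and February 2015. Regions were compared in their seasonal difference, over the mean of the 13 months and within each month. Consecutive months were compared within each region, and so were February 2015 and February 2014. The day of the annual peak came from a cosine and sine of 365 days per region. It was compared over probes with an adjusted p under 0.05 and an amplitude of at least 0.5 in each region. These contrasts, thresholds and seasons, and the alternatives that follow, were fixed before the data were examined.

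Several measures were added after the data were seen. A season index placed each array between the winter mean (0) and the summer mean (1) of the 3 regions, as the median over the probes called between summer and winter. The days on which a region's index passed 0.5 in spring and autumn were interpolated between sampling days. Their spread was taken from 1000 draws of 1 array per group. Probes higher or lower in spring or autumn than in both other seasons were counted. The lag between winter-high and summer-high probes was computed in both transitions. The fry test of limma asked whether the probes called between summer and winter moved, on balance, in 1 direction between 2 regions within a month. Its p was adjusted over 39 tests, and it was read only for the months outside the defined summer and winter.

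The probe names are contig names followed by an unexplained 4-place letter code. The files pair no probe with a gene, and 0 of the 19304 names matched the reference table of gene symbols for the assembly Sugi_1.0. The gene lists drawn up in advance, including those for the circadian clock and for pollen cones, and their camera tests therefore could not be run. The rule for naming was, in the absence of descriptions, at most 2 contigs that were higher and 2 that were lower in each contrast, by largest log2 difference. They were taken among called probes with the same sign in each region (season, and the pair of Februaries) or in at least 11 of the 13 months (regions). For the seasonal contrast, each region also had to pass an adjusted p under 0.05.

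Alternatives for normalization were quantile normalization, scaling to the median, the deposited series table, and normexp background correction with an offset of 50. The column of mean spot brightness named for normexp in advance is absent from the files, so the median spot brightness was used. Other alternatives were no filter, probes above background on all arrays, no minimum change, blocks for replicate number, title code and slide, arrays of 1 region only, other months for the seasons, a half-year term and a larger amplitude for the peak day, and leaving out each array in turn. Blocks for the scan run, a random block for the slide, and fits without pairs of months were added after the data were seen.

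The calls were tested on simulated data with 16128 probes and the spread of the real ones. At a log2 difference of 1.5, the contrast of summer and winter recovered 98% of the changed probes, and a comparison of 2 regions within March recovered 72%. At a difference of 3 the latter recovered 96%. The test of region by month recovered 46% at 1.5 and 90% at 3. A simulated shift of the annual curve by -10 days was found as -10.3 days. For the crossings of the season index, a simulated shift of 10 days in spring was found as 8.98 days and a shift of -10 days in autumn as -11.5 days. Figures were drawn with matplotlib 3.10.9.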

Results

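Expression was measured through a year in the branch tips of Japanese cedar growing in 3 Japanese regions, from Yamagata in the north through Ibaraki to Kumamoto in the south. Each of the 13 months from February 2014 to February 2015 had 2 samples per region, so that a region had 26 arrays and the series 78. Of the 19304 probes, 16128 were tested. The number of probes well above background on an array ran from 12197 to 16168, with a median of 14165. A larger share was above background in summer than in winter in each region. In Yamagata the shares were 75.4% ± 3.53 (SD, n = 6) and 68.0% ± 3.08 (SD, n = 8), in Ibaraki 75.4% ± 2.32 and 69.7% ± 3.89, and in Kumamoto 78.8% ± 3.48 and 71.3% ± 1.49. The summer arrays were also brighter, with a mean 75th percentile of 706 intensity units against 538 in Yamagata, 701 against 642 in Ibaraki and 982 against 681 in Kumamoto. In Ibaraki the SD was 172 in summer and 222 in winter. From winter to summer the share thus rose together with the mean brightness. The Ibaraki arrays of the other months went the other way: they were dimmer than in winter, at 603, with a larger share of 73.9%. Samples of the same region and month correlated over the tested probes at 0.963 to 0.993, with a median of 0.985, and probes are not independent replicates. The files pair no probe with a gene, so the values below describe probes and the contigs they were designed from.

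The year in the branch tip was mainly a single swing between a summer state and a winter state. The first principal component carried 66.4% of the variance and the second 5.97%. Most probes changed with the months: 13449 probes (83.4%) changed over the 13 months in Yamagata, 12715 (78.8%) in Ibaraki and 11933 (74.0%) in Kumamoto, by the moderated F test of limma. Of these, 10564 were called in all 3 regions and 14784 in at least 1.

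The comparison of June to August with the winter months asked which transcripts belong to the growing season and which to the cold one. Most of the changes were shared by the regions, with 5272 probes called in the same direction in each of the 3, while the size of the change differed for 1394 to 1777 probes between pairs of regions. Averaged over the regions, 6917 probes differed, 3815 of them higher in summer and 3102 lower. Differences were often large, with 2230 probes more than 4-fold higher and 1169 more than 4-fold lower in summer. Yamagata had 7364 called probes (4010 higher, 3354 lower), Ibaraki 6865 (3624 higher, 3241 lower) and Kumamoto 6982 (3980 higher, 3002 lower).

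Of the shared probes, 3020 were higher in summer and 2252 lower, where independent calls would give 222 and 125. Only 28 probes were called in opposite directions in different regions. Across probes, the seasonal differences of the regions correlated at 0.943 for Yamagata with Kumamoto, 0.943 for Yamagata with Ibaraki and 0.957 for Ibaraki with Kumamoto. On slides that held summer and winter arrays of the same region, between 96.7% and 98.7% of the probes called without that slide had the same sign within it. The majority of higher calls depended on the scaling of the arrays and on the filter: 55.2% of the calls were higher in summer with 75th percentile scaling, 46.7% with quantile normalization, 47.0% with median scaling and 41.7% among probes above background on all arrays.

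Some transcripts behaved as switches, near background for one part of the year and bright in the other. The contig reCj31485 was above background on all 24 winter arrays and on 0 of 18 summer arrays. It was 8995-fold lower in summer relative to a floor (adjusted p 2.0e-45 in limma for the fitted difference). The contig reCj00026 was above background on 24 of 24 winter and 1 of 18 summer arrays, and was 3043-fold lower in summer relative to the floor. In the other direction, reCj32458 was 1515-fold higher in summer relative to the floor, above background on 18 of 18 summer and 1 of 24 winter arrays. The contig reCj15288 was 935-fold higher in summer relative to the floor, above background on 18 of 18 summer and 0 of 24 winter arrays. The floor is the lowest signal of any probe well above background on an array, taken in place of a dimmer signal of the contig. It is not the detection limit of the contig itself, so these folds are not strict lower bounds. With normexp background correction, which compresses dim signals, the log2 differences of the 4 contigs were -10.22, -8.65, 8.03 and 7.33.

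**Figure D1:**
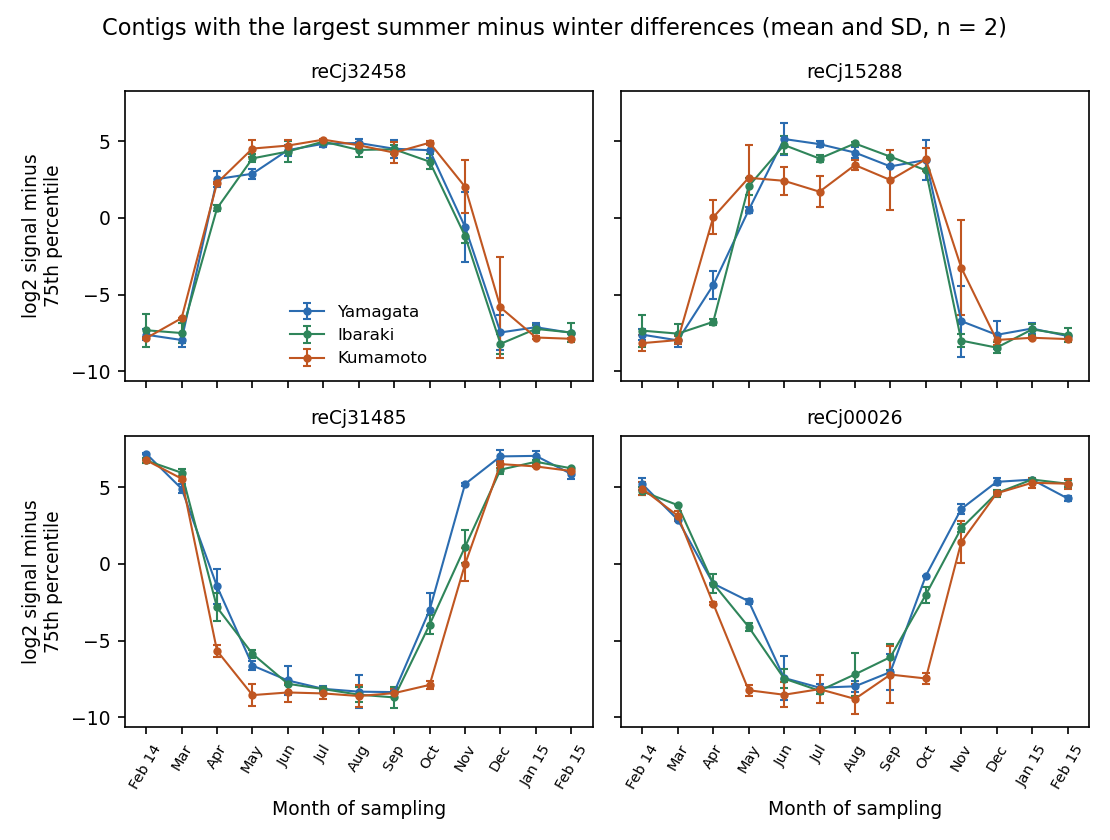
Mean log2 signal relative to the 75th percentile of the array, by month of sampling, for the 2 contigs most raised and the 2 most lowered in summer. Points are means and bars the SD of n = 2 samples per region and month; reCj31485 was above background on 24 of 24 winter and 0 of 18 summer arrays.

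Expression moved between the states mainly in spring and late autumn, and changed little in summer in Yamagata and Kumamoto but not in Ibaraki. The step from March to April was the largest of the year in Yamagata and Ibaraki, with 5299 and 3637 called probes. In Ibaraki this order rests on 1 array, since without Ibaraki March replicate 1 the count was 3144, under the 3341 of November to December. It was 3621 in Kumamoto, where the largest step was November to December with 4236. Other steps were large too. From February to March 2014, 3471 probes changed in Yamagata, and of those that also differed between summer and winter 1335 moved toward the summer level and 711 toward the winter level. From April to May 2309 changed in Ibaraki, and from December to January 1997 in Kumamoto. Of the March to April calls that also differed between summer and winter, 3740 of 3871 moved toward the summer level in Yamagata, 2991 of 3033 in Ibaraki and 3208 of 3237 in Kumamoto. From September to October, 1123 probes changed over 34 days in Yamagata and 30 over 25 days in Kumamoto, where leaving out 1 array gave 3 to 409, so the intervals compared were not of the same length. Ibaraki lay between them with 756 over 36 days, or 197 and 486 without Ibaraki September replicate 1 or October replicate 1.

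From October to November 2962 probes changed in Yamagata, 2243 in Ibaraki and 3187 in Kumamoto. Without Ibaraki October replicate 1 or November replicate 1 the Ibaraki count was 1238 or 1492, and without Kumamoto November replicate 1 the Kumamoto count was 2025. From November to December the counts were 3687, 3341 and 4236. Of the October to November calls that also differed between summer and winter, 2614 of 2642, 1935 of 1978 and 2672 of 2735 moved toward the winter level. In the step that followed it was 2791 of 2867, 2513 of 2612 and 3156 of 3265. From June to July, 4 probes changed in Yamagata and 8 in Kumamoto, and from July to August 60 and 4. These counts stayed at 64 or fewer whichever array was left out. At an unadjusted p under 0.05 the June to July steps had 929 and 1174 probes. Ibaraki was different, with 945 from June to July (227 to 1595 without 1 array) and 1294 from July to August (204 to 1355).

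**Figure D2:**
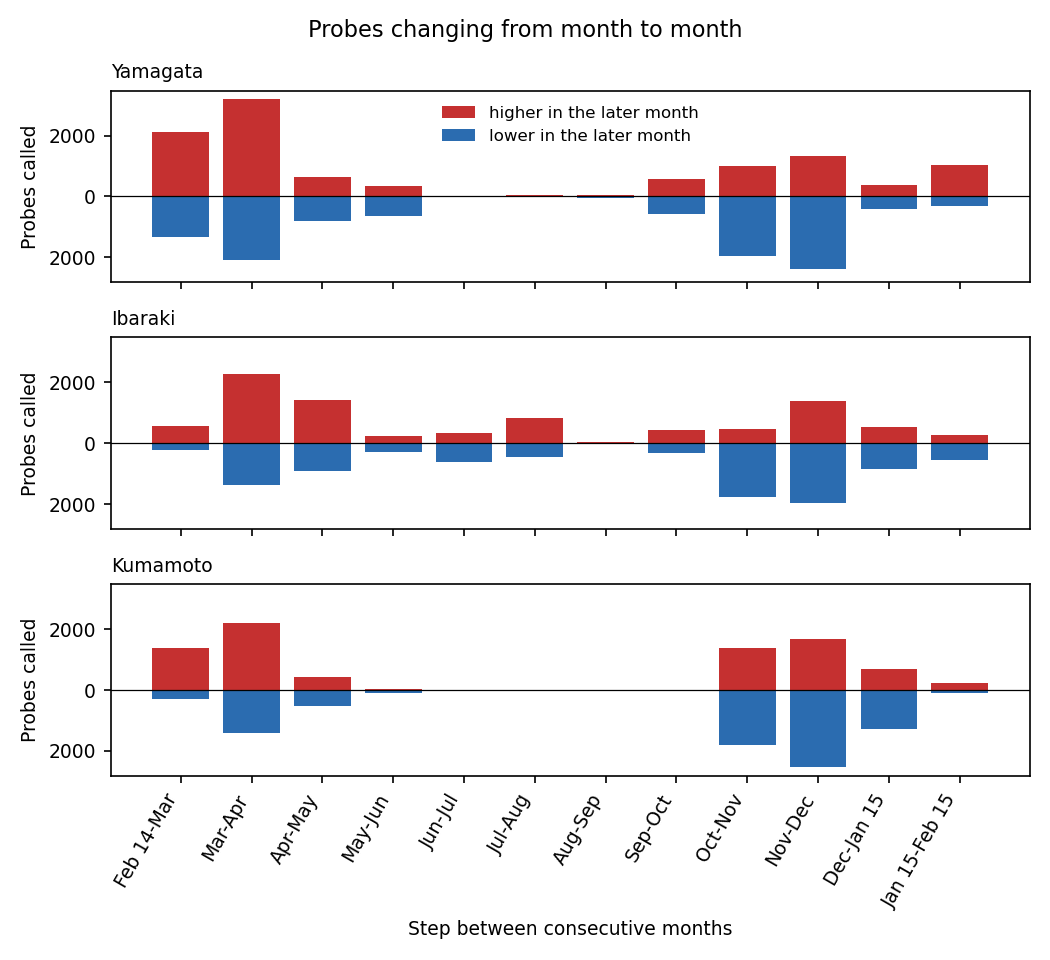
Number of probes called between consecutive months in each region, with those higher in the later month above the line and those lower below it. The March to April step had 5299 calls in Yamagata, 3637 in Ibaraki and 3621 in Kumamoto, and the June to July step had 4, 945 and 8.

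A small group of probes stood highest or lowest in the transitions in the mean of the 3 regions. The pattern was not required in each region or month. Over the 3 regions, 115 probes were higher in spring (March to May) than in both summer and winter, and 16 were lower. In autumn (September to November) 110 were higher and 38 lower than in both. Leaving out any array gave 104 to 124 and 99 to 124 for the probes that were higher. The counts were smaller where dim signals carried less weight: among probes above background on all arrays 26 were higher and 1 lower in spring and 9 higher and 20 lower in autumn, and with normexp it was 46 and 1 in spring and 37 and 12 in autumn.

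How the 3 sites differed in the timing of the year was asked with the season index, which runs from 0 at the winter mean to 1 at the summer mean. Kumamoto, in the south, passed the midpoint of the index earliest in spring and last in autumn. Its index passed 0.5 on day 81.6 of 2014 (SD of the draws 1.04), against day 90.9 (0.303) in Yamagata and day 92.7 (0.466) in Ibaraki. In autumn the index fell through 0.5 on day 303 (1.25) in Yamagata, day 313 (0.382) in Ibaraki and day 318 (3.71) in Kumamoto.

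The time on the summer side was 213 days in Yamagata, 220 in Ibaraki and 236 in Kumamoto. Yamagata minus Kumamoto was -23.5 days (SD of the draws 3.97), Ibaraki minus Kumamoto -16.2 days (3.91) and Yamagata minus Ibaraki -7.38 days (1.45), so each difference exceeded the spread between replicates. The Kumamoto samples of November lay furthest apart in the index (SD 0.102, n = 2), and without replicate 1 or 2 of that group Yamagata minus Kumamoto was -26.7 or -19.3 days. Ibaraki minus Kumamoto was then -19.3 or -11.9 days. The autumn part of the latter, -5.10 days, fell to -0.845 without replicate 2.

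**Figure D3:**
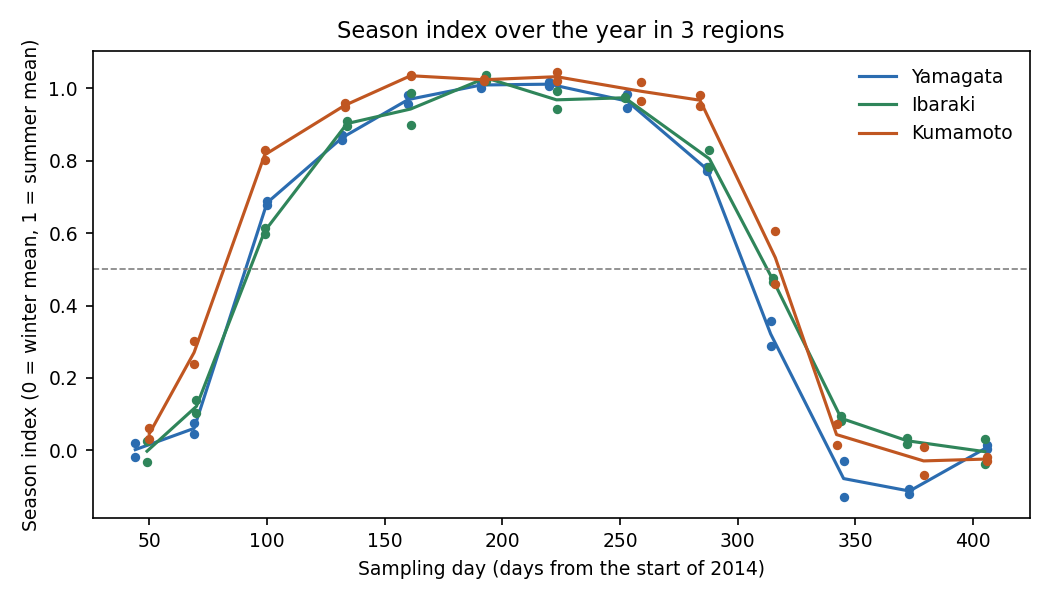
Season index, in units of the summer minus winter difference, by sampling day counted from the start of 2014. Points are the 2 arrays of a group and lines join their means; the dashed line at 0.5 was passed on days 81.6, 90.9 and 92.7 in spring in Kumamoto, Yamagata and Ibaraki.

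Within single months the shift could be seen without interpolation, though a shift within a month does not tell timing from a difference in level. In March, 76.6% of the seasonal probes that differed between Yamagata and Kumamoto were nearer the winter level in Yamagata (fry in limma, adjusted p 2.1e-06), and in April 89.6% (adjusted p 0.00033). In May it was 67.4% (adjusted p 0.022), in October 97.3% and in November 96.5% (adjusted p 1.2e-06 in each). The median over all seasonal probes was a log2 difference of -0.39, -0.28, -0.23, -0.41 and -0.44 toward winter in these 5 months. September showed no such shift (adjusted p 0.44), but Kumamoto was sampled 6 days later than Yamagata in that month, against at most 3 days apart in the other 5. Against Kumamoto, Ibaraki was nearer winter by fry in March (93.6%, adjusted p 8.4e-05), April (92.8%, 3.4e-06) and October (90.0%, 2.2e-05). In October Ibaraki was sampled on day 288 and Kumamoto on day 284, so the later date may add to that shift. For this pair May (60.6%, adjusted p 0.25), September (82.4%, 0.44) and November (74.0%, 0.11) did not pass 0.05 in fry.

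A smooth annual curve gave smaller differences in the date of the centre of the year, which depended on the form of the curve. Over 6591 probes the median peak day of Yamagata minus Kumamoto was -3.48 days (SD of the draws 1.59), of Yamagata minus Ibaraki -6.19 days (0.971) and of Ibaraki minus Kumamoto 2.22 days (1.57). With a half-year term added, Yamagata minus Kumamoto was 0 and Ibaraki minus Kumamoto 7.5 days. With 1 array left out, Yamagata minus Kumamoto ran from -6.02 to -1.30 days. Leaving out any month left the signs as they were, with ranges of -7.70 to -4.86 days for Yamagata minus Ibaraki and 0.264 to 4.31 days for Ibaraki minus Kumamoto. Without Kumamoto April replicate 2, Ibaraki minus Kumamoto was -0.275 days, so its direction rests on single arrays. Fitted peaks gathered in January and July, with 28.1% and 30.1% of the probes in Yamagata, 25.9% and 25.7% in Ibaraki and 29.4% and 32.4% in Kumamoto.

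The size of the seasonal change was also compared between regions. It differed for 1777 probes between Yamagata and Kumamoto, and was the larger one in Yamagata for 1042 of them. Between Yamagata and Ibaraki it differed for 1689 probes, with the larger change in Yamagata for 1181. Between Ibaraki and Kumamoto it differed for 1394 probes, with the larger change in Kumamoto for 879. The 2 differences had opposite signs for 428, 396 and 472 of these probes. With February 2014 left out of the winter, Yamagata against Kumamoto had 1129, and without June and August 2014, Ibaraki against Kumamoto had 560. Fewer samples and the loss of these months go together, and the cause was not tested. The course over all months differed between regions for 8015 probes (49.7%), by the F test of region by month.

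Differences between regions came and went with the months and were fewest in September. Between Yamagata and Kumamoto 4328 probes differed in February 2014 and 3581 in March, and between Yamagata and Ibaraki 4016 and 2732. Leaving out any array kept these 4 counts at 3775 or more, 3171 or more, 3637 or more and 2182 or more. In those months Ibaraki and Kumamoto differed in 886 and 822 probes, with 380 and 408 as the lowest counts without 1 array. In February 2014 Yamagata was sampled on day 44, Ibaraki on day 49 and Kumamoto on day 50. In March the days were 69, 70 and 69. In September the pairs had 5, 50 and 54 calls (Yamagata with Kumamoto, Yamagata with Ibaraki, Ibaraki with Kumamoto). Without Kumamoto September replicate 1 the pairs with Kumamoto had 300 and 343, and at an unadjusted p under 0.05 the 5 calls of Yamagata with Kumamoto became 1700.

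For Yamagata with Kumamoto the other months, from April 2014, had 619, 1761, 660, 130, 40, 926, 1021, 1861, 1797 and 1195 calls, September being given above. For Yamagata with Ibaraki they had 709, 289, 754, 341, 836, 756, 1222, 2345, 1876 and 893, and for Ibaraki with Kumamoto 1458, 1507, 2837, 954, 1459, 1224, 536, 1136, 429 and 348. Many of these single-month counts rested on 1 of the 4 arrays. The June count of Ibaraki with Kumamoto was 619 without Ibaraki replicate 1 and 391 without Kumamoto replicate 2. The August count was 124 without Ibaraki replicate 2, and the count of Yamagata with Ibaraki in August was then 88.

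**Figure D4:**
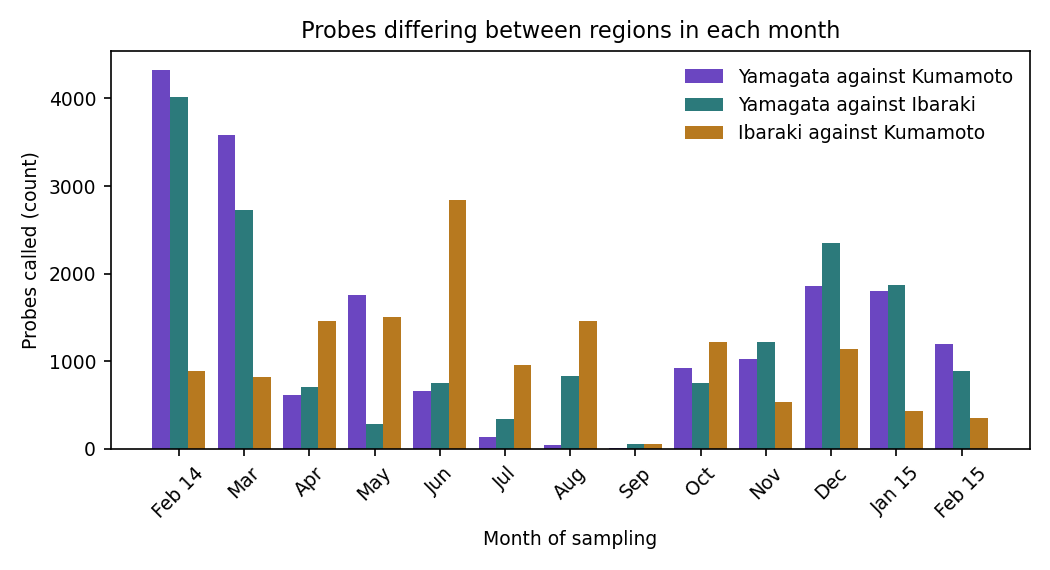
Number of probes called between each pair of regions in each month, with bars starting at 0. The pairs with Yamagata stood at 4328 and 4016 in February 2014, and in September 2014 the 3 pairs had 5, 50 and 54 calls.

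Averaged over the 13 months, few probes differed between regions by the minimum change of 2-fold, although 9123, 7656 and 9954 of the 16128 passed the adjusted p alone (Yamagata minus Kumamoto, Yamagata minus Ibaraki, Ibaraki minus Kumamoto). Yamagata minus Kumamoto had 300 calls (227 higher, 73 lower), Yamagata minus Ibaraki 263 (103 higher, 160 lower) and Ibaraki minus Kumamoto 251 (191 higher, 60 lower). The balance turned for Yamagata minus Ibaraki with normexp (32 higher, 18 lower) and for Ibaraki minus Kumamoto with the slide as a fixed block (338 higher, 353 lower). On slides that held both regions, the probes called from the other slides had the same sign within the slide in 81.6% to 95.7% of cases for Yamagata minus Kumamoto, 81.4% to 88.8% for Yamagata minus Ibaraki and 64.7% to 95.1% for Ibaraki minus Kumamoto. Against Kumamoto, Yamagata was highest in reCj32787 and reCj30769. Of summer and winter, the former differed mainly in winter and the latter mainly in summer. The spring and autumn months also enter the difference over the year, so it is not confined to those seasons. The contig reCj32787 had log2 means of 1.43 in Yamagata and -4.28 in Kumamoto in winter and of -6.75 and -6.93 in summer, and was above background on 16 and 14 of 26 arrays. For reCj30769 the winter means were 5.52 and 5.27 and the summer means -0.65 and -8.00, with 26 and 18 of 26 arrays above background. Yamagata was lowest in reCj17316, at -2.04 (SE 0.15), and reCj23484, at -1.41 (SE 0.12), the latter -0.75 with normexp and then no longer called.

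Most contigs named next were at background on many arrays, so their differences have no exact size. Against Ibaraki, Yamagata was highest in reCj29052, above background on 15 of 26 Yamagata and 4 of 26 Ibaraki arrays, and in reCj14221, on 21 and 12. The contigs reCj29690 and reCj27593 were the lowest in Yamagata, above background on 10 and 19 of 26 arrays there and on 25 and 25 in Ibaraki, and the highest in Ibaraki against Kumamoto, where it was 16 and 18. With the slide as a fixed block reCj29690 was no longer called for Ibaraki minus Kumamoto (2.09). Ibaraki was lowest against Kumamoto in reCj19188 and reCj18448, above background on 15 and 16 arrays in Ibaraki and 21 and 19 in Kumamoto. With normexp the values of the latter pair were -0.62 and -0.83 and not called.

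The series holds February of 2 successive years. The February 2015 arrays of all regions were on the same pair of slides and in the same scan run. Of the February 2014 arrays only Ibaraki replicate 2 shared a slide and the scan run with them. The year thus largely goes together with the slide and the scan run. It also goes together with the age of the cuttings and the date within February. Counted from the start of 2014, the days were 44 and 406 in Yamagata, 49 and 405 in Ibaraki and 50 and 406 in Kumamoto. The date was thus earlier in 2015 in each region, and least so in Yamagata. In Ibaraki and Kumamoto the Februaries differed in fewer probes than in Yamagata. Averaged over the regions 1131 probes differed, 517 higher and 614 lower in 2015. Yamagata alone had 3707, Ibaraki 697 and Kumamoto 964. With the slide or the scan run as a fixed block, Yamagata had 3372 or 3388. The Ibaraki count fell to between 252 and 394 without any 1 of its 4 February arrays. Without Kumamoto February 2015 replicate 2 or February 2014 replicate 2 the Kumamoto count was 238 or 472, and without February 2015 replicate 1 it was 1502. The contigs most raised in 2015 were reCj19463, by a log2 difference of 3.63 relative to the floor used for the seasonal contigs (above background on 3 of 6 arrays in 2014 and 6 of 6 in 2015), and reCj30813 (4 of 6 and 6 of 6). The rise of reCj30813 was almost wholly in Yamagata, from a dim signal in 2014 to a log2 mean of 4.85, while Ibaraki had 5.67 and 5.70 and Kumamoto 4.67 and 5.04. The most lowered, relative to the same floor, were reCj32909, at -5.09 (above background on 5 of 6 arrays in 2015), and reCj31867, at -4.86 (3 of 6). The fitted value of reCj32909 was -3.45 without Kumamoto February 2015 replicate 2 and -7.23 without replicate 1, and with the slide as a fixed block it was -5.02 and no longer called.

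**Figure D5:**
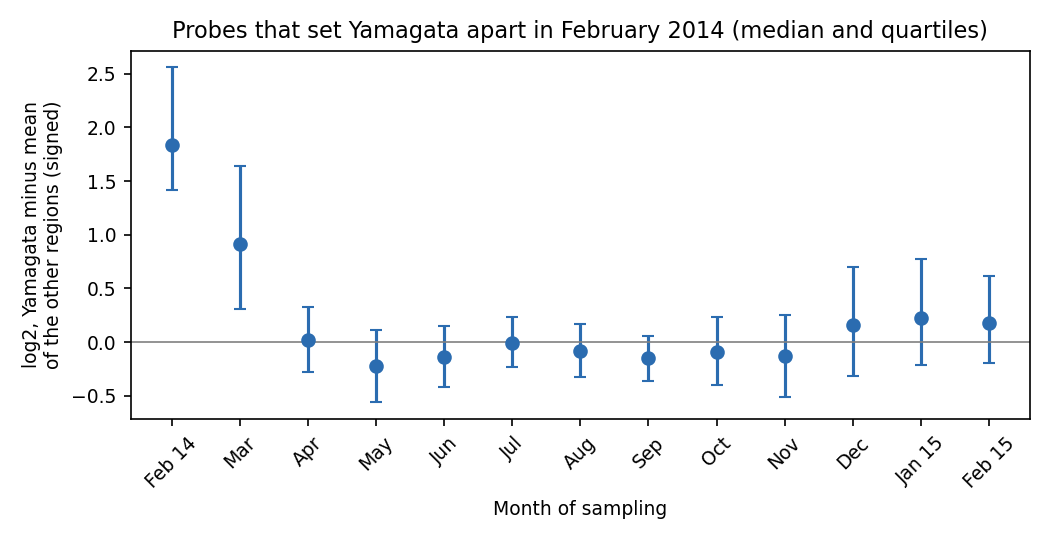
Log2 difference of Yamagata from the mean of the other regions, by month, for the 2922 probes called in February 2014 against both other regions, each signed so that February 2014 is positive. Points are medians and bars the quartiles over probes: 1.83 in February 2014, 0.91 in March 2014 and 0.17 in February 2015.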

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

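The tests of dim arrays, of the spacing of the sampling days, of the direction of the June difference and of the slide and single arrays in August were chosen after the result was seen. Groups of 2 samples are too small for a rule on outlying samples. The results that follow stood out because the same comparison came out differently in different regions, by a test of the difference itself.

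The seasonal difference differed between Yamagata and Kumamoto for 1777 probes, between Yamagata and Ibaraki for 1689 and between Ibaraki and Kumamoto for 1394. The course over the months differed for 8015 probes. The change from February 2014 to February 2015 differed for 3542 probes between Yamagata and Kumamoto, for 3824 between Yamagata and Ibaraki and for 699 between Ibaraki and Kumamoto. For the comparisons of at least 3 arrays per side, 100 splits of the arrays were fitted, and the real split was the only 1 as large in each. The highest other counts were 427, 405 and 832 for the seasonal differences and 4227 for the course over the months. A shuffled split mixes months or regions within a group, which widens the spread and lowers its count. The splits thus show that single arrays were not interchangeable. They cannot exclude a chance effect of a sampling day or site, which the arrays of a group share.

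The real split was also the only 1 as large for the counts that follow, with the same limit. For summer against winter the highest other split gave 2556 in the 3 regions together, against the real 6917. Within Yamagata, Ibaraki and Kumamoto it gave 5394, 5058 and 5130, against 7364, 6865 and 6982. Splits that call this many probes point to a structure of the samples, since a split that happens to follow the season calls seasonal probes. For the F tests over the months the highest others were 4148, 122 and 2804, against 13449, 12715 and 11933. For the regions over the year they were 56, 44 and 45, against 300, 263 and 251, and over all region pairs and months 17635 against 48393. The pair of Februaries gave 931 at most, against 1131. The probes higher in spring or in autumn had 0 in every other split, against 115 and 110, and those lower had at most 0 and 1, against 16 and 38. Splits were not run for the monthly steps, the single region pairs, the days of the season index or the peak days.

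Yamagata stood apart in February and March 2014: 2922 probes were called in February against both other regions in the same direction, 1325 of them higher and 1597 lower. A slide effect would have removed the difference, but with the slide as a fixed block 4437 probes were called between Yamagata and Kumamoto in February, against 4328, and 3565 in March, against 3581. Between Yamagata and Ibaraki it was 3762 against 4016 and 2973 against 2732. The arrays were not dim, with 70.5% of probes above background on average. The other winter and March arrays had a median of 70.9% and a lowest value of 63.2%. Of the 4 arrays, 4 had their nearest array within Yamagata, in their own group. This argues against an exchange of single arrays, but would not show an exchange of whole groups. Yamagata was sampled earlier in February 2014 (day 44, against 49 in Ibaraki and 50 in Kumamoto), which may add to the February difference and was not tested. In March the days were 69, 70 and 69, so their spacing does not account for the March difference. For these probes a difference of that size did not return, since their median difference was 0.17 in February 2015 against 1.83 in February 2014. They were chosen by their difference in February 2014, so part of the fall was built in. In December, January and February 2015, 58.6%, 64.3% and 62.4% of them had the same sign, while their median was negative in each month from May to November. A weaker difference that returns in winter thus stays open. Over all probes Yamagata did differ in the later winter too, with 1861 and 2345 calls against Kumamoto and Ibaraki in December, 1797 and 1876 in January and 1195 and 893 in February 2015, where Ibaraki with Kumamoto had 1136, 429 and 348, so a winter difference in other probes stays open. The same sign in March for 85.3% of the probes would fit a state of the Yamagata trees shared by 2 sampling days. It was not a steady one, since the median difference was 0.91 in March and 3471 probes changed between these days in Yamagata. Thus a biological cause such as the weather may be behind it, though the files do not record the weather and it was not tested. Planting in the year before was shared by the 3 regions.

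Ibaraki stood apart in June and August 2014. In July its pairs also had more calls, 954 with Kumamoto and 341 with Yamagata, than Yamagata with Kumamoto (130), but the 954 fell to 75 without Kumamoto July replicate 2. The probes called in June against both other regions had a median difference of 0.14 in July and 1.32 in August, and one of 0.51 in April, 0.58 in May, 0.52 in October and 0.52 in November. The test of the slide cannot decide for June. With the slide as a fixed block 3982 probes were called between Ibaraki and Kumamoto, against 2837, and 859 between Yamagata and Ibaraki, against 754. However, Ibaraki June replicate 2 was the only array of the series on its slide, so this block leaves the Ibaraki June mean to replicate 1. For August the slide stays open as well: Ibaraki with Kumamoto rose from 1459 to 1845, but Yamagata with Ibaraki fell from 836 to 385. A slide effect and a difference of Ibaraki thus cannot be told apart in that month. The size of the June difference rests largely on 1 array, with 619 calls without Ibaraki June replicate 1 and 3402 without the other, and with 391 and 3818 without Kumamoto June replicate 2 and replicate 1. The same holds for August, with 124 calls between Ibaraki and Kumamoto without Ibaraki August replicate 2 and 909 without the other. The direction in June does not rest on 1 Ibaraki array: of the 508 probes called in August against both other regions, 97.0% or more had the same sign on each Ibaraki June array. Both arrays were compared with the same June mean of the other regions, so a deviating array of those regions is not covered. The June and August differences correlated at 0.76 across probes, the highest of 78 month pairs. In Yamagata and Kumamoto the June and August arrays were on the same slides, as was replicate 1 of both months in Ibaraki. The July arrays were in part on other slides. July was less alike (June with July 0.30, July with August 0.27), while June correlated with May at 0.53 and with October at 0.41, and August with November at 0.50 and with September at 0.46. The correlations were computed without taking out the slide, so the shared slides and a state shared by the June and August samples cannot be told apart. Such a state, for example of the weather or the hour of sampling, was not tested, since neither is recorded. A difference of Ibaraki that runs through more of the year stays open as well.

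Kumamoto spent more days on the summer side of the season index than Yamagata. The scaling of the arrays does not account for this, since the difference was -22.4 days at its nearest to 0 over the scalings, and the slide does not, since with a fixed block it was -25.9 days against -23.5. The spacing of the sampling days does not either: of the months outside summer and winter, 5 were sampled at most 3 days apart in the regions, and 5 of 5 showed the shift toward winter in Yamagata. The technical explanations tested are thus excluded, and a hypothesis is that the longer warm season of the southern site may lengthen the summer state. Temperature was not recorded in the files, so the hypothesis was not tested, and the origin of the cuttings stays open too.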

How the results depend on the processing

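Fits with the scan run as a block, without pairs of months, and with each region on its own scale were chosen after the data were seen, as were all results of the season index. Of 270 values of the main counts under the alternatives, 217 stayed within 1.5 times of the reported count, 36 were lower and 17 higher. In all 1326 counts with 1 array left out (the lone array being assumed to vary like the other groups), the count stayed within 1.5 times. The replicate block changed no main count beyond that, with 8025 probes for region by month against 8015. The gene lists and their camera tests were not run, since no probe could be paired with a gene.

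With probes above background on all arrays fewer probes were tested. The seasonal counts were then 8695 in Yamagata, 7886 in Ibaraki and 7182 in Kumamoto, region by month 4507, and summer against winter 3419 in the 3 regions and 3812, 3390 and 3438 in each. The seasonal difference differed for 676 probes (Yamagata against Kumamoto), 613 (Yamagata against Ibaraki) and 340 (Ibaraki against Kumamoto), and the regions over the year for 45, 33 and 29. The pair of Februaries had 350, the region pairs 23682 and the monthly steps 24557. For Yamagata minus Ibaraki the peak day was -7.73 and the days above the midpoint -10.3.

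Normexp compresses dim signals. It gave 4724 for region by month, 4442 for summer against winter, 4756 in Yamagata and 4221 in Ibaraki, and in the order above 640, 614 and 416 for the seasonal differences and 104, 50 and 37 for the regions over the year. The Februaries had 402, the region pairs 23793, the steps 29847, and the peak day of Yamagata minus Ibaraki was -5.16. Signal over background thus limits which probes are called. Without the minimum change more probes were called: 14084 for summer against winter, 12969, 12829 and 12822 within regions, 5754, 5099 and 3886 for the seasonal differences, 9123, 7656 and 9954 for the regions over the year, 5179 for the Februaries, 98127 for the region pairs and 103634 for the steps. The days above the midpoint of Yamagata minus Ibaraki were then -9.32.

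With the slide as a fixed block, Ibaraki against Kumamoto rose to 2226 for the seasonal difference and 691 over the year, and Yamagata minus Kumamoto over the year to 493; the cause was not tested. The scan run moved the days of Yamagata minus Ibaraki to -4.93, and scaling each region on its own moved them to -4.23 and those of Yamagata minus Kumamoto to -18.8; the cause was not tested. With other months the cause was not tested either, since fewer samples and the loss of the months that stood apart go together. Winter without February 2014 gave 1129 for Yamagata against Kumamoto, and July and August against January and February 2015 gave 1116, and 377 for Ibaraki against Kumamoto. Without February and March 2014 the values were 1113 for Yamagata against Kumamoto, 5079 for region by month, 377 for Ibaraki minus Kumamoto over the year and 0.586 for its peak day. Without June and August 2014, Ibaraki against Kumamoto had 560.

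The peak day depended on the form of the curve and on single arrays. With a half-year term Yamagata minus Kumamoto was 0 and Ibaraki minus Kumamoto 7.5 days, and with an amplitude of at least 1 Yamagata minus Ibaraki was -4.96; the cause was not tested. With 1 array left out it ran from -6.02 to -1.30 for Yamagata minus Kumamoto, -7.73 to -4.72 for Yamagata minus Ibaraki and -0.275 to 4.68 for Ibaraki minus Kumamoto, each end from an April or October array. The days above the midpoint ran from -26.7 to -19.3 for Yamagata minus Kumamoto and -19.3 to -11.9 for Ibaraki minus Kumamoto.

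The lag of winter-high probes in autumn changed its sign. It was -3.72 days in Yamagata, -0.300 in Ibaraki and -4.15 in Kumamoto, and with normexp 2.33, 9.15 and 6.62. In Ibaraki it was also 3.73 with quantile normalization and 0.159 with median scaling, and ran from -0.684 to 0.130 with 1 array left out; the cause was not tested.

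Scaling moved the median of all probes between summer and winter from a log2 of -0.05 to -0.20 (quantile), -0.24 (median) and -0.17 (normexp), so directions are relative to it. The share of higher calls moved by more than 10 points in these cases. For the seasonal difference of Ibaraki against Kumamoto it went from 29.6% to 48.8% with quantile, 59.4% with normexp, 170 of 340 calls above background on all arrays and 42.2% without the minimum change. For Yamagata against Ibaraki it went from 53.6% to 29.2% with normexp and 64.1% without June and August. Over the year, Ibaraki minus Kumamoto went from 76.1% to 61.3% (quantile), 100% (normexp), 96.6% (above background on all arrays), 48.9% (slide as a fixed block) and 49.4% (no minimum change). Yamagata minus Kumamoto went from 75.7% to 97.1% (normexp), 63.1% (slide) and 44.1% (no minimum change), and Yamagata minus Ibaraki from 39.2% to 64.0% (normexp) and 18.4% (without February and March 2014). The Februaries went from 45.7% to 32.3% with normexp. Summer against winter went from 55.2% to 41.7% above background on all arrays, with 42.5%, 40.5% and 41.8% in Yamagata, Ibaraki and Kumamoto, and in Kumamoto from 57.0% to 47.0% with quantile.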

Other observations

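The lag between the probes high in winter and those high in summer was noticed in the data, and both of its tests were planned after that and before their values were known. In spring, winter-high probes passed the middle of their range 7.92 days after summer-high probes in Yamagata (SD of the draws 1.08), 5.93 days after them in Ibaraki (2.17) and 5.82 days after them in Kumamoto (2.24). The hypothesis was that the winter programme may be shut down more slowly than the summer programme starts. It was not upheld. Over the background alternatives the smallest lag was 1.24 days (normexp, Kumamoto), where normexp gave 6.22 in Yamagata and 13.5 in Ibaraki. Among probes above background on all arrays the lags were 7.55, 8.18 and 7.50 days in Yamagata, Ibaraki and Kumamoto. The smallest over the scalings was 1.51 days (quantile normalization, Ibaraki). Both smallest lags lay under the spread of the draws. Neither reached 0, so signal near background and the scaling of the arrays cannot be told apart from a real lag. The lag in autumn changed its sign with the processing.

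Over the letter codes in the probe names, which are unexplained, the share of tested probes called between summer and winter ran from 31.3% (MSWR, 2933 probes) to 72.8% (M---, 136 probes), against 42.9% of all tested probes. The letters also went with brightness, with a mean log2 signal of -0.69 for probes with an S and -3.49 for those without, and no test was run.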
